A study of Zingiber officinale with 24 samples.

How the data were processed

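The deposited data are 24 two-colour Agilent arrays of yellow ginger, each with a Cy3-dyed and a Cy5-dyed RNA sample. Per the labels, total RNA was prepared with a Qiagen RNeasy Plant kit from frozen tissue, amplified to aminoallyl RNA and coupled to dye. Per the file headers, the slides were read on a GenePix 4000B scanner and quantified with Agilent Feature Extraction 9.5.3.1 for array design 020086. The deposited scanner files hold, per the file headers, the intensity of each spot in both channels, as the mean pixel brightness and as the median of the local background. They also hold processed intensity values, which Feature Extraction subtracted for background with spatial detrending and normalized between dyes with linear and lowess steps, and their log10 ratio of Cy5 over Cy3. How probe sequences were chosen is not given in the sources used here.

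A value table deposited with the series holds log10 ratios. Of its 24 columns, 22 equal the log10 ratios of their own scanner file within 1e-05, which settles their scale and direction. The columns of root 2 months against rhizome 2 months and of rhizome 2 months against rhizome 4 months hold each other's values (0.743% equal to the own file, r = 0.2624 across probes). With predictions fitted on the other arrays, the scanner file recorded for root 2 months against rhizome 2 months had r = 0.621 with its own title and r = -0.193 with the other. The file recorded for rhizome 2 months against rhizome 4 months had r = -0.14 and r = 0.0383. The scanner files were therefore used as recorded, and the exchanged order was run as an alternative. Column medians ranged from -0.02819 to 0.07665, and no further centring was found.

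Arrays were assigned by the titles, which name the condition of each dye. Signals were corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50, mean signal and median local background), and log2(Cy5/Cy3) was normalized within each array by loess with a span of 0.3. Control spots had weight 0 in loess and were left out afterwards. Spots with a non-uniformity mark had weight 0, and saturated spots stayed. Files were read with the R package data.table, version 1.17.8. Of 15744 spots, 536 were controls and 15208 were probes, with 1 spot each. A probe was tested if it was well above background in over 0.5 of the channels of at least 1 of the 9 conditions, which left 14898 and removed 310. Of the tested probes, 10319 carried a name other than unknown or hypothetical. Names are those of the array design, which rest on similarity to genes of other plants and can be old. None was matched to the reference gene table, because the probe names share no identifier with it.

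The median signal per channel was 193.7 to 3516 (median 1111), 5.782 to 87.9 times the background (median 31.32). Between 84% and 99.6% of the probes of a channel were well above background (median 93.3%), 0 to 217 were saturated, and 34 to 3350 spots of an array were non-uniform. In none of 18 tests for an outlying array (9 conditions, 2 measures of signal) did one stand apart. Arrays whose file headers share a scan date were taken to lie on the same slide, which gave 5 slides with 1 to 8 arrays each. The arrays of root 2 months against rhizome 2 months and of rhizome 2 months against rhizome 4 months each were alone on a slide. A dye intercept per slide therefore gives these arrays no weight in a contrast.

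All 24 arrays entered one limma model with a term per condition and a dye intercept, with 15 residual degrees of freedom, a prior of 1.998 and a median residual SD of 0.4688. The median SE was 0.205 for leaf against rhizome, 0.2435 for rhizome of 7 against 2 months and 0.3104 for rhizome of 4 against 3 months. Tissue contrasts averaged the ages of 2 and 7 months. A contrast between age changes was the difference of 2 such changes, and rhizome-higher probes had to pass in 4 contrasts. P-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. For a probe not above background in any channel of a condition, the fold is a lower bound from separate channels after loess and Aquantile, with the dim side set to the higher of its own signal and the lowest signal well above background on each array. It is open to dye bias where the dyes are not balanced.

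Lists of genes (25, matched to probe names by word patterns) were tested with camera at a preset correlation of 0.01, in 10 comparisons, with adjustment over the lists of a comparison. Their calls were set against camera with an estimated correlation and against fry, which tests whether a list moves one way without comparing it to other probes. These alternatives used no spot weights, so non-uniform spots counted in full there but not in the main calls. Both camera and fry passed 42 of 250 tests, but in different comparisons. By camera and by fry these were 6 and 16 for leaf against rhizome, 0 and 7 for root against rhizome, 11 and 15 for leaf against root, and 4 and 2 for rhizome of 7 against 2 months. They were 3 and 1 for leaf age, 6 and 0 for root age, and 3 and 0, 2 and 0, 4 and 1, and 3 and 0 for the neighbouring rhizome ages in order. The word patterns also caught names outside the theme of a list, so list counts and shifts include such probes. Examples are methylenetetrahydrofolate reductase among jasmonate and ethylene genes and a T-complex protein 1 subunit among homeotic and meristem regulators.

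Named genes followed a rule. For each comparison they were the 8 largest positive and 8 largest negative differences past the threshold with a gene name, 1 probe per name, for which every array holding both conditions had the sign of the fit after the dye effect was subtracted. Contrasts between age changes have no such arrays, so this sign was not checked there. Up to 4 members of each list with the smallest adjusted p were added, passing or not, and the 12 rhizome-higher probes with the largest minimum difference. The model, the probe filter, the lists, this rule and the alternatives, apart from those said below to be later choices, were fixed before the data were examined.

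The steps were tested on simulated data in which 200 of the 14898 probes had known differences, 50 per size. Noise was normal and independent between probes and arrays, at each probe's SD from the fit, without slide effects or an array in doubt. The shares below show the steps under these settings, and not the error rate in the real data. At true log2 differences of 1, 2, 3 and 4 the share recovered was 56%, 94%, 96% and 100% for leaf against rhizome. It was 52%, 86%, 100% and 98% for root against rhizome, and 36%, 80%, 98% and 98% for rhizome of 7 against 2 months. It was 38%, 82%, 94% and 98% for rhizome of 4 against 3 months, 46%, 82%, 90% and 98% for leaf of 7 against 2 months, and 38%, 88%, 88% and 100% for root of 7 against 2 months. Of the calls, 4.95%, 3.45%, 6.02%, 4.88%, 4.82% and 2.48% in the same order were unchanged probes. A photosynthesis list shifted by 0.5 was called by camera, with 1 of the other lists.

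The alternatives were no background correction, Agilent's processed signals, median centring in place of loess, scale normalization between arrays, the value table, other probe filters, no dye term, array weights, the slide as a random block or with its own dye intercept, and separate channels. Others averaged both arrays labelled leaf 2 months against root 7 months, left out each array in turn, left out the array whose tissue label differs from its title, used stricter thresholds, or fitted each loop alone. Chosen after the data were seen were the exchange of 2 scanner files, fits without those arrays and others in doubt, each of the slides numbered 3 and 4 alone, and a fit without the probes whose names end in _s (1175) or _as (793), endings whose meaning is not given in the sources used here.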

Results

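Gene expression was measured in leaf, root and rhizome of yellow ginger, Zingiber officinale, whose rhizome is an underground stem that stores starch and the aromatic compounds of the spice. Each of the 24 arrays compared a Cy3-dyed RNA sample with a Cy5-dyed one, and the samples came from 9 conditions. These were rhizome at 2, 3, 4, 6 and 7 months of plant age, and leaf and root at 2 and 7 months. The hybridisations formed one loop through the rhizome ages and another through the tissues, joined at the youngest and oldest rhizome. Rhizome of 7 months was on 8 arrays, rhizome of 2 months on 7, leaf of 2 months on 6, leaf of 7 months and root of either age on 5, and each other rhizome age on 4. The median signal of a channel ranged from 193.7 to 3516 intensity units, and 84% to 99.6% of the probes of a channel were well above background. Of 15208 probes, 14898 were tested. The number of arrays limits the precision. Nothing in the labels says that the arrays of a condition used separate plants, so the p-values measure only the spread between these arrays, which may be technical. Differences are log2 values ± SE from limma, with adjusted p-values over all tested probes, and gene names are those the array design gave to its probes. Saturated spots kept their value, so the size of a difference is inexact where a probe was saturated in some channels. The numbers of such channels are given for the genes most affected.

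Probes for photosynthesis genes, which mark green tissue, lay at a median intensity percentile of 56 to 71.9 in 10 of the 11 leaf channels and of 25.3 to 39.1 in the 36 root and rhizome channels of the 23 other arrays. The Cy3 channel of the array labelled leaf 2 months against root 7 months, replicate 2, was the exception among leaf channels, at 30. This array is called the array labelled replicate 2, and it stayed in the fits on all 24 arrays, with counts without it given beside those it moved by over 1.5 times. The array titled rhizome 4 months against rhizome 6 months carries leaf as its tissue label. Its photosynthesis probes lay at 26.9, within the 26.1 to 31.1 of the 9 other rhizome-only arrays.

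**Figure D1:**
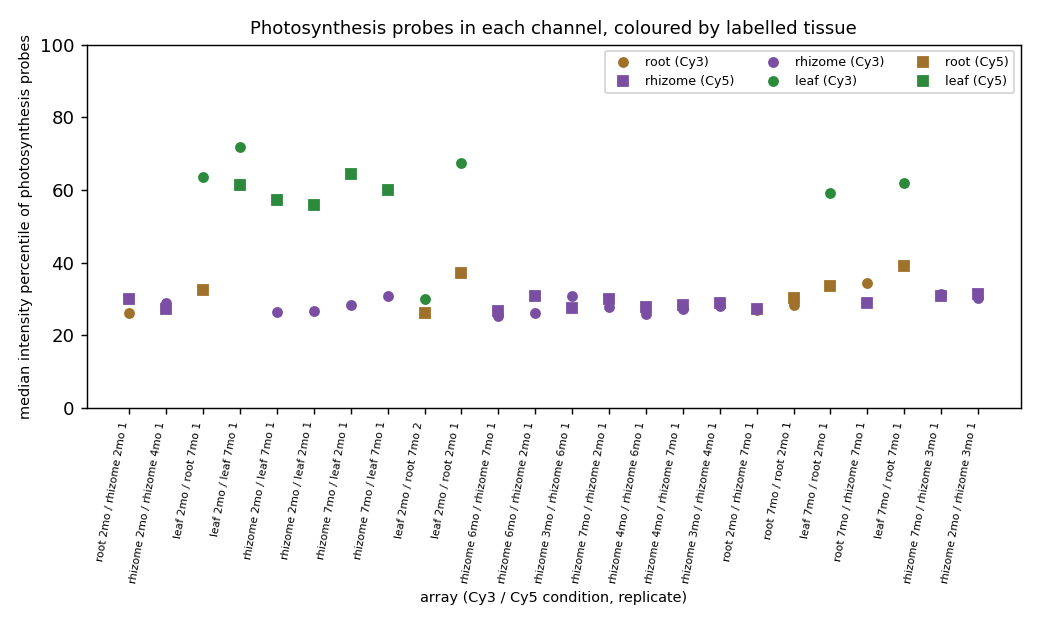
Median intensity percentile of the photosynthesis probes (y axis, percent) in the Cy3 channel (circles) and the Cy5 channel (squares) of each array (x axis), coloured by the labelled tissue. Leaf channels lie at 56 to 71.9 except the Cy3 channel of the array labelled replicate 2, which lies at 30 among the root and rhizome channels.

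Leaf was set against rhizome, averaged over plants of 2 and 7 months, to find the genes that separate the green organ from the storage organ. Photosynthesis genes led the leaf side. A light-harvesting chlorophyll a-b binding protein (probe pGT1_00059_10) was higher in leaf by 7.84 ± 0.70 (229-fold, adjusted p = 3.44e-07, 11 leaf and 15 rhizome channels, saturated in 7 of the leaf channels), and the antenna protein LHCII type III by 7.11 ± 0.66. Plastidic glutamine synthetase, which assimilates ammonium in the chloroplast, was higher by 6.92 ± 0.55 (saturated in 4 of 11 leaf channels), and the Calvin cycle enzyme phosphoribulokinase by 6.50, with 14 of 15 rhizome channels above background. On the rhizome side stood enzymes that make sesquiterpenes, the volatile hydrocarbons of ginger oil: delta-cadinene synthase (pGT1_06930_01) was lower in leaf at -7.15 ± 1.0 (adjusted p = 2.9e-05), where 9 of 11 leaf channels were above background, and sesquiterpene synthase (pGT1_01729_01) at -6.51 ± 0.83 (adjusted p = 9.46e-06).

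Of the 195 photosynthesis probes, 107 were higher in leaf and 16 lower (126 changed when adjusted over the list alone). The list as a whole was higher by camera (adjusted p = 3.10e-09), a call lost with an estimated correlation (adjusted p = 0.306 with an estimated correlation). Chlorophyll and carotenoid synthesis was also higher, with 19 of 45 probes up and 2 down (20 adjusted over the list alone; camera adjusted p = 0.00471; adjusted p = 0.364 with an estimated correlation). Its members included phytoene synthase at 6.23, which opens carotenoid synthesis, and magnesium chelatase at 4.78 (saturated in 5 of 11 leaf channels), which opens the chlorophyll branch. The cell wall list was lower in leaf, with 80 of 155 probes down and 13 up (93 adjusted over the list alone; camera adjusted p = 2.49e-07; adjusted p = 0.306 with an estimated correlation). An extensin-like wall protein was at -6.46 ± 0.85 (saturated in 7 of 15 rhizome channels), a polygalacturonase at -3.5 and cellulose synthases at -2.24 (9 of 11 leaf channels above background) and -2.54. Terpene synthases were lower at 9 of 15 probes and higher at 1 (11 adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.487 with an estimated correlation). Lectins and storage proteins were lower at 10 of 18 probes and higher at 1 (13 adjusted over the list alone; camera adjusted p = 0.00471; adjusted p = 0.306 with an estimated correlation), among them a mannose-binding lectin at -3.42. Sucrose metabolism was lower at 19 of 42 probes and higher at 7 (26 adjusted over the list alone; camera adjusted p = 0.0296; adjusted p = 0.306 with an estimated correlation). Sucrose synthases, which cleave incoming sucrose in storage organs, were at -4.72 and -4.68. Of the homeotic and meristem regulators 19 of 59 probes were lower and 14 higher (35 adjusted over the list alone; camera adjusted p = 0.502), with a median of 0.00532, a mean of -0.117 and a test pointing down. Those lower included Knotted 3 at -3.92 and the homeotic protein TKN1 at -3.32.

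In all, 3712 probes were higher in leaf and 3418 lower, 7130 together (limma, adjusted p under 0.05), and 4186 of them differed at least 2-fold. A separate dye intercept for each slide gave 3610. Within the 8 arrays of slide 3, which include the array labelled replicate 2 and where 2 residual degrees of freedom remained, limma called 0 with 547 at an unadjusted p under 0.05.

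Root was compared with rhizome in the same way, which sets the absorbing organ against the storage organ. The named genes on the root side included transporters and enzymes of nitrogen metabolism. The uptake and transport list as a whole had 13 of 89 probes higher and 11 lower (24 adjusted over the list alone; camera adjusted p = 0.606). The high-affinity nitrate transporter (pGT1_10716_01) was higher by 4.96 ± 0.54 (adjusted p = 1.72e-05, 10 root and 15 rhizome channels), its partner protein NAR2.3 by 4.94 ± 0.53, and glutamine synthetases by 4.81 and 4.28. A plasma membrane proton ATPase, which powers uptake, was higher by 5.0 ± 0.35, and a shaker-like potassium channel by 4.18. Among the named genes the largest positive difference was that of a ripening-associated protein, at 5.52 ± 0.42 (adjusted p = 1.3e-06), with 14 of 15 rhizome channels above background. The rhizome side was led by a Nod26-like protein (pGT1_02575_01), of the membrane channel family, at -6.68 ± 0.36 in root (102-fold, adjusted p = 4.42e-08).

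Single starch and homeobox genes were lower in root than in rhizome. Granule-bound starch synthase (pGT1_07125_01), which makes amylose, was at -5.28 ± 0.52 (adjusted p = 5.26e-06) and -5.0 on different probes, saturated in 4 and 3 of 15 rhizome channels, and a starch branching enzyme at -2.92. The KNOTTED-1-like homeobox gene, whose family maintains shoot meristems, was at -5.77 ± 0.82 (adjusted p = 0.000171). Xyloglucan endotransglycosylase, which remodels growing walls, was at -5.70 ± 0.46. Sesquiterpene synthases were at -4.47 and -4.25, whereas a germacrene D synthase was higher in root at 1.23. A dimeric mannose-specific lectin was higher in root by 4.82 ± 0.495, with 10 of 15 rhizome channels above background. No list as a whole passed camera in this comparison. Cell wall genes came nearest, with 29 of 155 probes lower and 6 higher (36 adjusted over the list alone; camera adjusted p = 0.0538). Starch synthesis had 3 of 9 probes lower and 0 higher (3 adjusted over the list alone; camera adjusted p = 0.0972). Homeotic and meristem regulators had 10 of 59 lower and 8 higher (19 adjusted over the list alone; camera adjusted p = 0.377).

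In all, 1470 probes were higher in root and 1443 lower, 2913 together, of which 1658 differed at least 2-fold. Without the array of root 2 months against rhizome 7 months the count was 1793. It was 628 with a dye intercept per slide, and 0 within slide 3 alone (limma, 76 at an unadjusted p under 0.05).

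Leaf was then compared with root. The leaf side again held the photosynthetic apparatus, with LHCII type III (pGT1_00666_02) at 5.93 ± 0.62, phosphoribulokinase at 5.81 ± 0.345 (adjusted p = 5.85e-09, above background in 11 of 11 leaf and 9 of 10 root channels) and a photosystem II core protein at 5.73. The root side included the plasma membrane water channels PIP1.5 at -5.82 (saturated in 9 of 10 root channels), PIP2-1 at -5.19 (saturated in 7) and PIP1.3 at -4.23. It also included glutamine synthetase N-1 at -6.61, the proton ATPase at -5.97 and a 23 kDa jasmonate-induced protein at -6.45. The ripening-associated protein (pGT1_03929_01) was at -7.31 ± 0.42 (adjusted p = 1.74e-08) and the dimeric mannose-specific lectin at -6.21 ± 0.467, each above background in 5 of 11 leaf channels.

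Of the 25 lists, 11 differed between leaf and root by camera, and each of these calls was lost with an estimated correlation. Photosynthesis was higher in leaf at 107 of 195 probes and lower at 15 (128 adjusted over the list alone; camera adjusted p = 1.76e-10; adjusted p = 0.219 with an estimated correlation). Chlorophyll and carotenoid synthesis was higher at 24 of 45 and lower at 2 (26 adjusted over the list alone; camera adjusted p = 8.73e-05; adjusted p = 0.158 with an estimated correlation). Starch genes were higher in leaf, the synthesis list at 6 of 9 probes (6 adjusted over the list alone; camera adjusted p = 0.00635; adjusted p = 0.224 with an estimated correlation) and the breakdown list at 6 of 14 (6 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.158 with an estimated correlation). ADP-glucose pyrophosphorylase, which feeds starch synthesis, was at 4.93 and isoamylase at 1.67. Heat shock and oxidative stress genes were higher at 73 of 245 and lower at 27 (100 adjusted over the list alone; camera adjusted p = 0.0161; adjusted p = 0.31 with an estimated correlation).

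The other 6 lists were lower in leaf than in root. Lectins and storage proteins were lower at 10 of 18 and higher at 2 (13 adjusted over the list alone; camera adjusted p = 8.61e-05; adjusted p = 0.125 with an estimated correlation), with lectins at -6.06 and -5.92. Cell wall genes were lower at 59 of 155 and higher at 10 (69 adjusted over the list alone; camera adjusted p = 8.73e-05; adjusted p = 0.31 with an estimated correlation). Terpene synthases were lower at 7 of 15 (10 adjusted over the list alone; camera adjusted p = 0.00475; adjusted p = 0.31 with an estimated correlation). Class III peroxidases, which cross-link wall phenolics, were lower at 28 of 64 and higher at 10 (39 adjusted over the list alone; camera adjusted p = 0.00768; adjusted p = 0.125 with an estimated correlation). Phenylpropanoid enzymes, which also feed gingerol synthesis, were lower at 15 of 46 and higher at 7 (22 adjusted over the list alone; camera adjusted p = 0.0348; adjusted p = 0.155 with an estimated correlation). Ribosomal proteins were lower at 127 of 375 and higher at 52 (181 adjusted over the list alone; camera adjusted p = 0.0131; adjusted p = 0.592 with an estimated correlation), while single members, 50S ribosomal proteins L10 and L12, were higher in leaf at 3.78 and 3.43.

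In all, 3209 probes were higher in leaf than in root and 2989 lower, 6198 together, of which 3390 differed at least 2-fold. The count was 4586 with a dye intercept per slide and the phenylpropanoid (camera adjusted p = 0.0835) and starch breakdown (camera adjusted p = 0.0546) calls were lost. Within slide 3 alone limma called 0 probes with 316 at an unadjusted p under 0.05. There 6 list calls were lost: phenylpropanoid (camera adjusted p = 0.18), starch synthesis (0.104), starch breakdown (0.127), peroxidases (0.387), stress (0.434) and ribosomal proteins (0.874), the last at a mean of 0.0716.

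**Figure D2:**
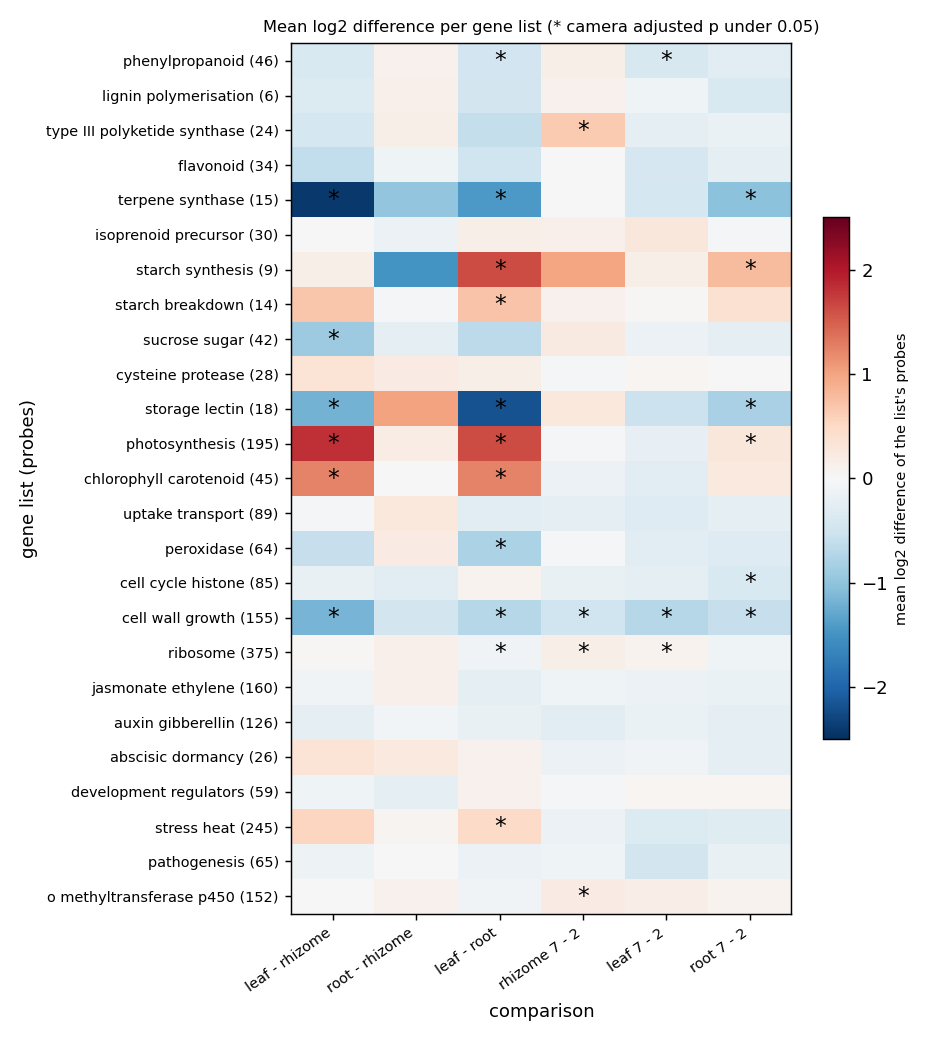
Mean log2 difference (colour, log2 units) of the probes of each gene list (y axis, number of probes in parentheses) in 6 comparisons (x axis). Asterisks mark a camera adjusted p under 0.05, as for photosynthesis in both comparisons of leaf with another organ.

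Across the 10 comparisons tested with lists, 42 of 250 list tests passed camera and 1 also passed with an estimated correlation. Under a dye intercept per slide 27 of these calls held and 15 were lost. Within slide 3 alone 18 held, 11 were lost and 1 turned, and within slide 4 alone 7 held, 7 were lost and 2 turned. Without the array labelled replicate 2 the list tests past camera numbered 33, the lowest count among fits that left out 1 array. Of 100 assignments of the condition pairs to the arrays, 15 gave at least 42 list calls, the real one included, with 53 as the highest of the others, so chance cannot be excluded for their number.

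Genes characteristic of the rhizome were those higher there than in both other organs at both ages. The largest smallest difference among the named genes was that of sesquiterpene synthase, at least 4.28 log2 units above leaf and root at 2 and at 7 months. An alcohol dehydrogenase homolog followed at 4.23, the KNOTTED-1-like homeobox protein at 4.20 and a lipid transfer protein at 4.11, the last at 3.11 without the array labelled replicate 2. An O-methyltransferase, of the family that decorates phenolic compounds, had a smallest difference of 3.76, a glutathione S-transferase of 3.71, and beta-1,3-glucanases, which act in defence and callose turnover, of 3.33 and 3.24. The former turned to -0.582 within slide 3 alone, whose 8 arrays include the array labelled replicate 2. A gibberellin-regulated protein (3.26) and the homeotic protein TKN1 (3.14) completed the named genes with a known family, beside a ripening-related protein (3.45).

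Altogether 247 probes met these 4 conditions. They included 8 of 155 cell wall probes and 5 of 59 probes of homeotic and meristem regulators (Fisher's exact test, adjusted p = 0.0542 for each), and 2 of 15 terpene synthases (adjusted p = 0.207), so no list was over-represented past the threshold. The count fell to 155 without the array of root 2 months against rhizome 2 months, 146 without rhizome 2 months against leaf 2 months, 123 without root 2 months against rhizome 7 months, 159 without root 7 months against root 2 months and 146 without root 7 months against rhizome 7 months. It was 16 with a dye intercept per slide and 0 within slide 3 alone, where limma called 0 probes in either tissue contrast with 547 for leaf and 76 for root at an unadjusted p under 0.05.

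Rhizome of 7 months was compared with rhizome of 2 months to follow the maturing storage organ. Agglutinin (pGT1_02245_01), a carbohydrate-binding storage protein, was higher by 4.67 ± 0.46 (25.5-fold, adjusted p = 0.00015, 8 and 7 channels), a lectin by 3.11 ± 0.55 (adjusted p = 0.00712) and a GNA-1 lectin by 3.02. Granule-bound starch synthase 1 (pGT1_14235_01) was higher by 4.16 ± 0.62 (adjusted p = 0.00252, saturated in 3 of 8 channels of 7 months) and a starch branching enzyme by 3.28 ± 0.62 (adjusted p = 0.009). A metallothionein-like protein, which binds metal ions, was higher by 3.11 ± 0.69 (adjusted p = 0.025). The named genes also held a rubisco activase probe (pGT1_00001_072_s), of the photosynthesis list, higher by 3.7 ± 0.84.

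Among secondary metabolism genes a chalcone synthase rose by 1.69 ± 0.46 (adjusted p = 0.039), anthocyanidin reductase by 1.87 ± 0.33 and a cytochrome P450 by 2.25. Another cytochrome P450 was not well above background in any of the 7 channels of 2 months and was at least 3.63-fold higher at 7 months, against the lowest signal well above background on each array (adjusted p = 0.00105). Genes lower in the older rhizome included a cytosolic class II small heat shock protein (pGT1_00185_02) at -4.19 ± 0.44 (adjusted p = 0.00105), the sulfate transporter ATST1 at -3.75 ± 0.72, a tonoplast water channel at -3.45 ± 0.87, and the transcription factor WRKY30 at -3.22 ± 0.91 (adjusted p = 0.049). A cellulose synthase was at -1.69 and an extensin-like protein at -2.06.

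Starch synthesis had 3 of 9 probes higher (4 adjusted over the list alone; camera adjusted p = 0.26) and lectins and storage proteins had 5 of 18 higher (7 adjusted over the list alone; camera adjusted p = 0.476), with no shift of either list as a whole past the threshold. Both had a negative median (-0.0606 and -0.395), a positive mean (0.977 and 0.26) and a test pointing up. The chalcone synthase family, which includes enzymes of the curcuminoid and gingerol type, shifted upwards with 1 of 24 probes past the threshold (1 adjusted over the list alone; camera adjusted p = 0.00421; adjusted p = 0.359 with an estimated correlation). O-methyltransferases and cytochrome P450s had 11 of 152 probes higher and 1 lower (13 adjusted over the list alone; camera adjusted p = 0.0193; adjusted p = 0.359 with an estimated correlation). Cell wall genes shifted downwards, with 10 of 155 lower and 5 higher (24 adjusted over the list alone; camera adjusted p = 0.00726; adjusted p = 0.76 with an estimated correlation). Ribosomal proteins shifted upwards, with 9 of 375 higher and 5 lower (8 adjusted over the list alone; camera adjusted p = 0.00795; adjusted p = 0.776 with an estimated correlation). No terpene synthase passed, with 0 of 15 probes by limma.

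In all, 492 probes were higher at 7 months and 445 lower, 937 together, of which 461 differed at least 2-fold. Leaving out single arrays gave 134 without rhizome 7 months against rhizome 2 months, which is the array that compares both ages directly, 515 without rhizome 2 months against leaf 7 months, 540 without rhizome 2 months against leaf 2 months, 606 without rhizome 2 months against rhizome 3 months, and 1637 (791 higher, 846 lower) without the array labelled replicate 2. With a dye intercept per slide the count was 658 and the list of O-methyltransferases and P450s no longer passed (camera adjusted p = 0.0645). That list was also lost within slide 3 alone (0.272), and the ribosome list within slide 4 alone (0.891, at a mean of -0.0195). The ribosome shift was small, at a mean of 0.147 with the slide as a random block and 0.13 with a dye intercept per slide. Limma called 0 within slide 3 and 0 within slide 4, with 673 and 2081 at an unadjusted p under 0.05.

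The 5 rhizome ages together give the course of this change. The level at 4 months rests on 4 arrays and is less sure. Their r with predictions fitted without each of them was -0.267 (3 against 4 months), -0.133 (2 against 4), -0.0312 (4 against 6) and 0.399 (4 against 7). Agglutinin stood 2.06, 1.52, 3.82 and 4.67 above its level at 2 months in rhizome of 3, 4, 6 and 7 months (adjusted p of the test over all ages = 0.00144), and granule-bound starch synthase 1 stood 2.47, 2.07, 3.02 and 4.16 above (adjusted p = 0.0292). The latter was saturated in 1 of 4 channels of 3 months, 1 of 4 of 6 months and 3 of 8 of 7 months, so its course is inexact there. The lectin stood 1.28, 2.16, 3.00 and 3.11 above (adjusted p = 0.0423). The class II small heat shock protein was at -3.02, -2.24, -1.45 and -4.19 (adjusted p = 0.012), and the uncoupling protein UCP5, a mitochondrial carrier, at -1.13, -0.85, -0.49 and -3.54 (adjusted p = 0.0293). These 5 of the 16 named genes passed the test over all ages.

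**Figure D3:**
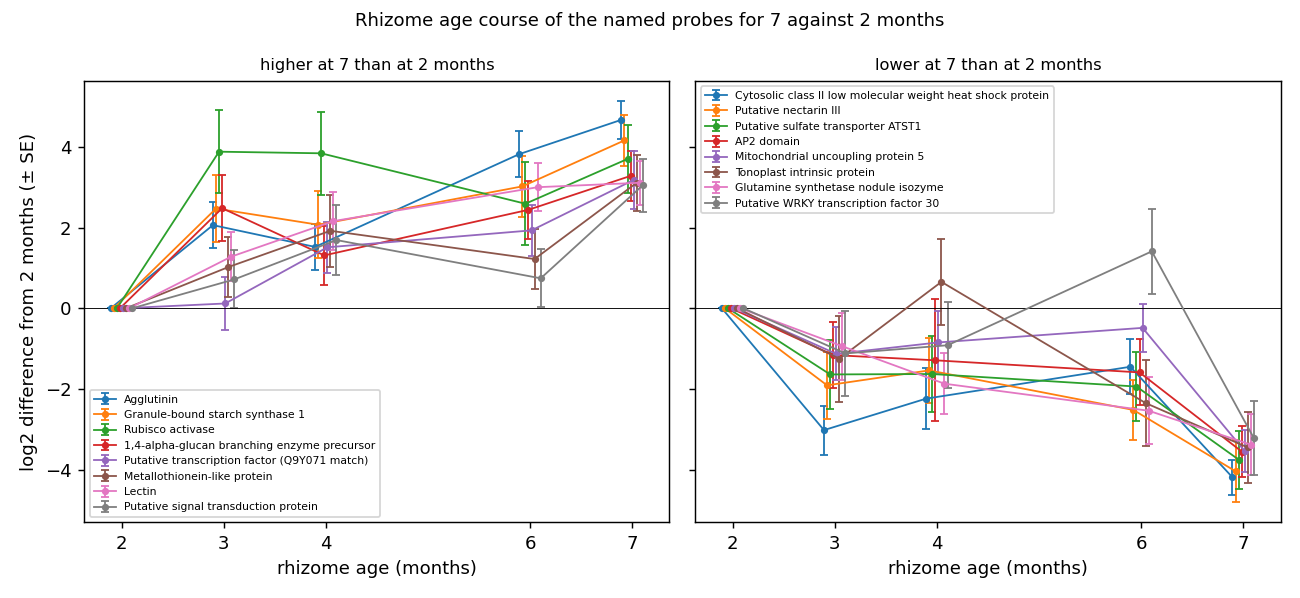
Log2 difference from rhizome of 2 months (y axis, log2 units, bars are SE) against rhizome age (x axis, months) for the 8 named genes higher at 7 months (left) and the 8 lower (right). Agglutinin and granule-bound starch synthase 1 lie above 0 at every later age, at 4.67 and 4.16 by 7 months.

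Over all 5 ages 139 probes changed, of which 71 also differed at least 2-fold between a pair of neighbouring ages. Of the 139, 51 were highest at 7 months and 33 at 2 months, and 53 were lowest at 7 months and 52 at 2 months. Leaving out single arrays gave 32 (without rhizome 7 months against rhizome 2 months) to 469 (without the array labelled replicate 2), and 15 of the 24 arrays moved it by over 1.5 times, 13 of them downwards. It was 109 with a dye intercept per slide and 0 within slide 4 alone, where limma's comparison of 7 with 2 months had 2081 probes at an unadjusted p under 0.05.

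Between neighbouring rhizome ages few single genes passed. Comparisons with rhizome of 4 months rest on the arrays whose r with their predictions is given above. From 4 to 6 months a transketolase (pGT1_10232_01), an enzyme of the pentose phosphate pathway, rose by 2.19 ± 0.24 and a transferase by 2.10 ± 0.24 (adjusted p = 0.0053 for both, 4 channels per age). From 6 to 7 months a nucleoside diphosphate kinase rose by 1.88 ± 0.30 (adjusted p = 0.0277, 8 and 4 channels). Over the same interval NPR1, a regulator of salicylic acid signalling, was at -1.84 ± 0.29 (adjusted p = 0.0364), a phosphofructokinase at -2.07 ± 0.37 (adjusted p = 0.047), and an AAA-type ATPase at -3.34 ± 0.51 (adjusted p = 0.0277) with 7 of 8 channels of 7 months above background.

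Shifts of whole lists were seen between neighbouring ages although 0 of their members passed over all probes. From 2 to 3 months ribosomal proteins shifted downwards (0 of 375 probes adjusted over the list alone; camera adjusted p = 4.51e-06; adjusted p = 0.637 with an estimated correlation), as did cell division genes (0 of 85 adjusted over the list alone; camera adjusted p = 0.023; adjusted p = 0.932 with an estimated correlation). Sucrose metabolism shifted upwards (0 of 42 adjusted over the list alone; camera adjusted p = 0.023; adjusted p = 0.454 with an estimated correlation), and turned to a mean of -0.603 within slide 4 alone. From 3 to 4 months cell division genes shifted downwards (0 of 85 adjusted over the list alone; camera adjusted p = 0.00516; adjusted p = 0.503 with an estimated correlation), a direction that turned to a mean of 0.114 without the array of rhizome 3 months against rhizome 4 months. Heat shock and oxidative stress genes shifted upwards (0 of 245 adjusted over the list alone; camera adjusted p = 0.000107; adjusted p = 0.253 with an estimated correlation).

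From 4 to 6 months ribosomal proteins shifted upwards (0 of 375 adjusted over the list alone; camera adjusted p = 4.83e-11; adjusted p = 0.231 with an estimated correlation) and stress genes downwards (1 of 245 adjusted over the list alone; camera adjusted p = 0.00375; adjusted p = 0.231 with an estimated correlation). Peroxidases shifted upwards (2 of 64 adjusted over the list alone; camera adjusted p = 0.00375), the single list call that held with an estimated correlation (adjusted p = 0.0405 with an estimated correlation), though it was lost within slide 4 alone. Auxin and gibberellin genes shifted downwards (0 of 126 adjusted over the list alone; camera adjusted p = 0.0158; adjusted p = 0.231 with an estimated correlation). From 6 to 7 months cell wall genes (2 of 155 adjusted over the list alone; camera adjusted p = 0.00606; adjusted p = 0.905 with an estimated correlation) and jasmonate and ethylene genes (0 of 160 adjusted over the list alone; camera adjusted p = 0.0467; adjusted p = 0.905 with an estimated correlation) shifted downwards. Cell division genes shifted upwards (0 of 85 adjusted over the list alone; camera adjusted p = 0.0467; adjusted p = 0.916 with an estimated correlation). By its word pattern the jasmonate and ethylene list also holds a methylenetetrahydrofolate reductase, and that of sucrose metabolism a Golgi nucleotide sugar transporter. With a dye intercept per slide the calls of sucrose metabolism (camera adjusted p = 0.999) and ribosomal proteins (0.435) from 2 to 3 months, and all 3 calls from 6 to 7 months (0.293, 0.0953 and 0.0953), were lost. Within slide 4 alone the camera direction of the cell wall list from 6 to 7 months turned, at a mean of -0.0279. Calls lost there were ribosomal proteins from 2 to 3 months (camera adjusted p = 0.812), cell division (0.868) and stress genes (0.242) from 3 to 4 months, peroxidases (0.164) and auxin and gibberellin genes (0.189) from 4 to 6 months, and jasmonate and ethylene genes (0.304) from 6 to 7 months.

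The counts of single probes were 0 from 2 to 3 months and 0 from 3 to 4 months (limma, 647 and 355 at an unadjusted p under 0.05). There were 2 from 4 to 6 months, both upwards, and 15 from 6 to 7 months, 1 upwards and 14 downwards. Without the array labelled replicate 2 they were 4, 0, 32 (12 upwards, 20 downwards) and 30 (4 upwards, 26 downwards). From 4 to 6 months single arrays gave 1 (without rhizome 4 months against 6 months) to 97 (without rhizome 6 months against 2 months), with 26 without rhizome 2 months against 4 months, 9 without rhizome 3 months against 4 months, 5 without rhizome 7 months against leaf 2 months and 4 without leaf 2 months against root 7 months, replicate 1. From 6 to 7 months they gave 0 (without rhizome 6 months against 7 months, or without rhizome 3 months against 6 months) to 173 (without rhizome 4 months against 6 months), and 16 of the 24 arrays moved the count by over 1.5 times. At 0 limma had 1046 and 1420 in this order at an unadjusted p under 0.05. A dye intercept per slide gave 2, 0, 3 and 9, and slide 4 alone gave 0 for each (limma, 994, 541, 1962 and 915 at an unadjusted p under 0.05).

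Leaf of 7 months was compared with leaf of 2 months for the effect of plant age on the green organ. GIGANTEA (pGT1_02834_01), a component of the circadian clock, was higher by 3.33 ± 0.33 (10.1-fold, adjusted p = 6.23e-05, 5 and 6 channels), and 3 of 5 GIGANTEA probes passed. A 1-deoxyxylulose 5-phosphate synthase, the entry enzyme of plastid isoprenoid synthesis, was higher by 3.22 ± 0.40 (adjusted p = 0.00554), and geranylgeranyl pyrophosphate synthase, a later enzyme, by 3.41 ± 0.66 (adjusted p = 0.0108). The isoprenoid precursor list, which holds the latter probe, had 1 of 30 higher (1 adjusted over the list alone; camera adjusted p = 0.189). A high mobility group protein, which binds chromatin, was higher by 3.5 ± 0.38 (adjusted p = 0.000346), a bZIP transcription factor by 3.46 and a rubisco probe by 3.64 ± 0.71 (adjusted p = 0.0121), the last 2 saturated in 2 of 5 channels of 7 months. Among the lower genes were a class IV chitinase at -3.96 ± 0.78 (adjusted p = 0.0272), above background in 3 of 5 channels of 7 months, and small heat shock proteins at -4.20 ± 0.90 and -4.03 ± 0.665.

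Cell wall genes were lower in the older leaf, with 12 of 155 probes down and 0 up (20 adjusted over the list alone; camera adjusted p = 0.000168; adjusted p = 0.731 with an estimated correlation). A fasciclin-like arabinogalactan protein was at -4.48 ± 0.97 (adjusted p = 0.016) and cellulose synthases were at -2.36 (3 of 5 channels of 7 months above background), -2.12 and -2.83. Phenylpropanoid enzymes were lower at 6 of 46 probes (7 adjusted over the list alone; camera adjusted p = 0.0362; adjusted p = 0.308 with an estimated correlation), among them 4-coumarate-CoA ligase at -2.22 (adjusted p = 0.000346), caffeoyl-CoA O-methyltransferase at -1.71 and phenylalanine ammonia-lyase, the entry enzyme, at -1.53. Ribosomal proteins shifted upwards with 5 of 375 probes higher (0 adjusted over the list alone; camera adjusted p = 0.0347; adjusted p = 0.835 with an estimated correlation). Pathogenesis-related genes had 9 of 65 lower and 1 higher (14 adjusted over the list alone; camera adjusted p = 0.189), and stress genes 19 of 245 lower and 7 higher (42 adjusted over the list alone; camera adjusted p = 0.247). Photosynthesis had 3 of 195 probes lower and 1 higher (1 adjusted over the list alone; camera adjusted p = 0.247), and 45 lower without the array labelled replicate 2.

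In all, 230 probes were higher in leaf at 7 months and 438 lower, 668 together, a split of 34.4% upwards that became 66.7% with scale normalization between arrays, where 42 passed. Single arrays gave 120 without leaf 2 months against leaf 7 months, the array that compares both ages directly, 310 without leaf 7 months against root 2 months, 410 without leaf 7 months against root 7 months, 426 without leaf 2 months against root 7 months, replicate 1, and 1524 (364 higher, 1160 lower) without the array labelled replicate 2. With a dye intercept per slide 19 passed and the phenylpropanoid and ribosome calls were lost (camera adjusted p = 0.222 for both). Both were also lost within slide 3 alone (0.841 and 0.628), ribosomal proteins at a mean of -0.0403. The ribosome shift was small, at a mean of 0.0747 with the slide as a random block and -2.74e-05 with a dye intercept per slide. Within slide 3 alone limma called 0 with 289 at an unadjusted p under 0.05.

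Root of 7 months was compared with root of 2 months. Far fewer probes passed, and most were lower in the older root. A terpenoid synthase (pGT1_09462_01) was at -4.53 ± 0.815 (adjusted p = 0.0209, 5 channels per age), a cellulase at -4.31 ± 0.89 (adjusted p = 0.0446), a type 2 metallothionein at -3.82 ± 0.64 (adjusted p = 0.0133) and an amino acid transporter at -3.73 ± 0.46 (adjusted p = 0.00104). Also lower were O-methyltransferases at -2.45 ± 0.24 and -3.53 ± 0.52 and a chalcone synthase at -2.60 ± 0.55 (adjusted p = 0.0425). The list of O-methyltransferases and P450s did not pass, with 1 of 152 higher and 2 lower (3 adjusted over the list alone; camera adjusted p = 0.142). Neither did that of the chalcone synthase family, with 1 of 24 lower (1 adjusted over the list alone; camera adjusted p = 0.624). It had a median of 0.0156, a mean of -0.167 and a test pointing down. Higher in the older root were a peroxidase at 3.13 ± 0.65 (adjusted p = 0.0425), a cytochrome P450 at 2.31 ± 0.46 (adjusted p = 0.032) and an acidic beta-1,3-glucanase at 1.08 ± 0.20.

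Cell wall genes shifted downwards in the older root, with 2 of 155 probes lower (8 adjusted over the list alone; camera adjusted p = 0.00123; adjusted p = 0.483 with an estimated correlation), and terpene synthases with 2 of 15 lower (6 adjusted over the list alone; camera adjusted p = 0.0177; adjusted p = 0.556 with an estimated correlation). Lectins and storage proteins shifted downwards with 0 of 18 passing (4 adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.415 with an estimated correlation), and cell division genes with 1 of 85 (1 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.669 with an estimated correlation), which turned to a mean of 0.161 within slide 3 alone. There root of 7 months was on 2 arrays, of which the array labelled replicate 2 is one. Photosynthesis (0 of 195, 0 adjusted over the list alone; camera adjusted p = 0.00665; adjusted p = 0.613 with an estimated correlation) and starch synthesis (0 of 9, 3 adjusted over the list alone; camera adjusted p = 0.0222; adjusted p = 0.415 with an estimated correlation) shifted upwards.

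In all, 9 probes were higher in root at 7 months and 63 lower, 72 together, a split of 12.5% upwards that became 31.2% with scale normalization, where 16 passed. Single arrays gave 25 without leaf 7 months against root 2 months, 44 without root 2 months against rhizome 2 months, 45 without root 2 months against rhizome 7 months, 116 without the array labelled replicate 2 and 403 without leaf 7 months against root 7 months. With a dye intercept per slide limma called 0 with 1052 at an unadjusted p under 0.05, and of the 6 list calls photosynthesis alone held there (camera adjusted p of the others 0.0561 to 0.869). The photosynthesis mean was 0.324 there and 1.07 within slide 3 alone. Both fits include the array labelled replicate 2, whose Cy3 channel lay at a photosynthesis percentile of 30, below the other leaf channels. Fitted as leaf of 2 months against root of 7 months, that array can raise these probes in root of 7 months. Whether the photosynthesis call holds without it is not given here. Starch synthesis (0.202) and lectins and storage proteins (0.6) were lost within slide 3 alone. Slide 3 alone gave 0 probes in limma with 512 at an unadjusted p under 0.05.

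Whether age acted alike in the organs was tested as a difference between their age changes. Agglutinin separated the rhizome from both other organs. It rose by 4.67 in rhizome and stood at 0.53 in leaf, a difference of -4.14 ± 0.71 taken as leaf minus rhizome (adjusted p = 0.0145). In root it stood at 0.97, a difference of -3.70 ± 0.69 (adjusted p = 0.0432). A lectin precursor differed between leaf and rhizome by -5.08 ± 1.02 (adjusted p = 0.0362). GIGANTEA rose more in leaf, by 2.45 ± 0.435 (adjusted p = 0.0173), as did the high mobility group protein, by 3.72 ± 0.48 (adjusted p = 0.00531). A chalcone synthase was at -2.60 with age in root and at 1.69 in rhizome, a difference of -4.29 ± 0.69 (adjusted p = 0.0174), and anthocyanidin reductase, an enzyme of flavonoid synthesis, differed by -2.81 ± 0.49 (adjusted p = 0.0362).

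The age change differed between leaf and rhizome at 88 probes, 24 towards higher and 64 towards lower in leaf, a split of 27.3% upwards, against 3 probes, all upwards, with scale normalization. It differed between root and rhizome at 20 probes, all towards lower in root, and at 55 without the array labelled replicate 2, 11 towards higher and 44 towards lower. For leaf and rhizome, 16 of the 24 arrays moved the count by over 1.5 times, from 9 without leaf 2 months against leaf 7 months to 781 without the array labelled replicate 2. For root and rhizome 15 arrays did, from 3 without root 7 months against root 2 months to 122 without leaf 7 months against root 7 months. With a dye intercept per slide limma called 0 and 0, with 1274 and 894 at an unadjusted p under 0.05. Slide 3 alone gave 0 and 0 in limma, with 270 and 226 at an unadjusted p under 0.05.

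**Figure D4:**
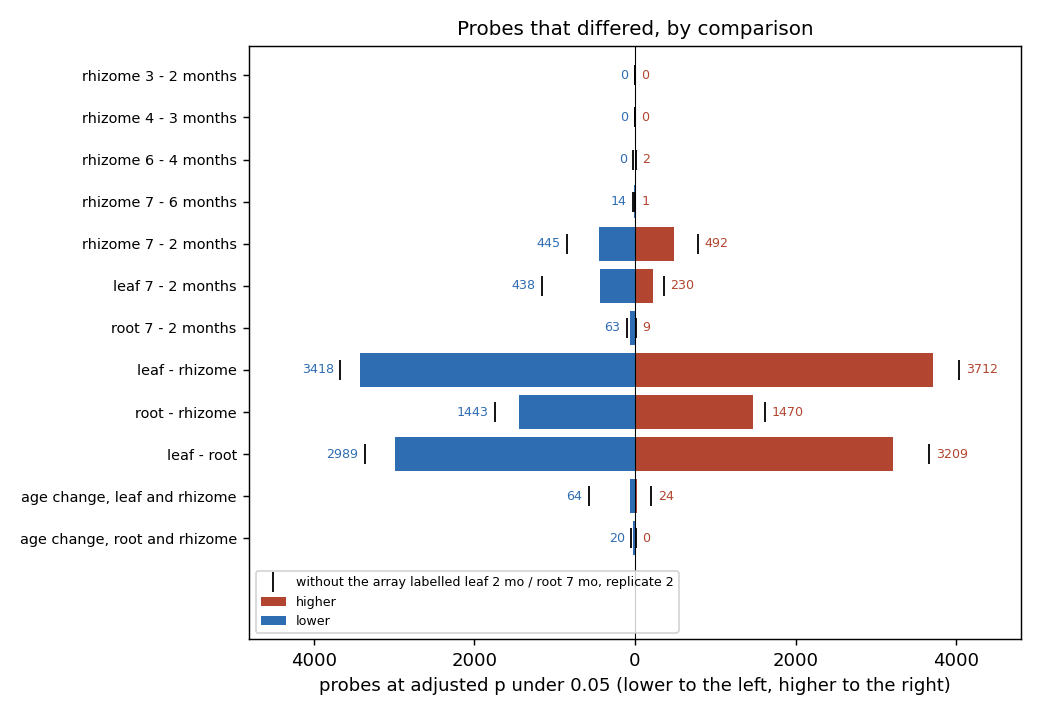
Number of probes past an adjusted p of 0.05 (x axis, higher to the right and lower to the left of 0) in each comparison (y axis), with the counts printed beside the bars. Black ticks mark the counts without the array labelled replicate 2, for example 364 higher and 1160 lower for leaf at 7 against 2 months, where all 24 arrays gave 230 and 438.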

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

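The fit of slide 3 alone and the reading of clock genes in rhizome and root were chosen only after the data were seen. The tests of differences between age changes, of their splits and of the hour of collection in leaf were planned.

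The change from 2 to 7 months differed between leaf and rhizome at 88 probes and between root and rhizome at 20 (limma, the difference itself tested). Of 100 assignments of the condition pairs to the arrays, 1 gave as many as 88, the real one, with 2 as the highest of the others. For root and rhizome 3 of 100 gave as many as 20, but 1 other assignment called 1881 probes, which points to a structure of the samples. Such a structure can be the tissue differences themselves, and what that assignment followed was not tested. Drawn assignments exchange tissues between arrays, so tissue differences enter their spread between arrays. The test therefore asks whether the titles bear on the arrays, and cannot decide whether age acted differently in the organs. Without the array labelled replicate 2 the count was 55, 11 towards higher and 44 towards lower in root. A dye intercept per slide left limma calling 0 and 0 (1274 and 894 at an unadjusted p under 0.05).

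Higher with age in leaf relative to rhizome was NAC2, a transcription factor of a family active in senescence, by 5.03 ± 1.06 (adjusted p = 0.0498), from 2.32 in leaf and -2.71 in rhizome. The high mobility group protein differed by 3.72, a putative alpha-glucosidase by 3.45, a hypersensitive-induced response protein by 2.86, an expressed protein by 2.51 and a cytochrome P450 by 2.44. A Gigantea-like protein differed by 2.5 ± 0.315 (adjusted p = 0.00311) and GIGANTEA by 2.45. The sign of the hypersensitive-induced response protein turned within slide 3 alone, at -0.383, in a fit that includes the array labelled replicate 2 as leaf of 2 months. Without that array, on the 23 others, it was 2.76 (adjusted p = 0.0241).

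Lower with age in leaf relative to rhizome was a putative signal transduction protein, at -5.66 ± 1.09 (adjusted p = 0.0498), from -2.61 in leaf and 3.05 in rhizome. Its size is inexact, since the probe was saturated in 6 of 12 channels on one side of the contrast and 5 of 14 on the other. A lectin precursor was at -5.08 and an elicitor-inducible cytochrome P450 at -4.66. A carboxyphosphonoenolpyruvate mutase was at -4.40, an S-RNase binding protein at -4.20 and agglutinin at -4.14. Plastidic glucan phosphorylase, which releases glucose phosphate from starch, was at -3.97 ± 0.803 (adjusted p = 0.039), from -1.27 in leaf and 2.70 in rhizome. A chitinase was at -3.82, from -3.55 in leaf and 0.27 in rhizome.

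Lower with age in root relative to rhizome were an auxin-induced protein at -4.37 ± 0.743 (adjusted p = 0.0432), chalcone synthase at -4.29, agglutinin at -3.70 and a 37 kDa chloroplast envelope polypeptide at -3.20. Anthocyanidin reductase was at -2.81, the transcription factor lim1 at -2.54, an ER lumen protein-retaining receptor at -2.53 and an O-methyltransferase at -2.46, the last from -2.45 in root and 0.01 in rhizome.

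GIGANTEA probes were higher in leaf at 7 than at 2 months, 3 of 5 past the threshold and a median of 3.16, with a PRR probe higher by 2.95 and 1 of 6 CONSTANS probes lower. GIGANTEA follows the time of day, so leaves collected at different hours are a candidate explanation, under which LHY, a clock gene with the opposite phase, would be lower. The median of the LHY probes was -0.137, from -0.722 to 1.29, and none of 3 passed, so the test does not decide. In rhizome of 7 against 2 months the LHY and GIGANTEA medians had the directions that different hours would give. LHY had a median of -1.07 (2 of 3 probes below 0, 1 past the threshold) and GIGANTEA of 0.69 (1 of 5 below 0, none past it). There 1 of 2 PRR probes was higher, and 6 of 6 CONSTANS probes lay below 0, as in leaf. In root the GIGANTEA median was 1.11 and the PRR median 1.05, but the LHY median was 0.376, with none of these probes past the threshold. The hour of collection and the age of the plant both stay open.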

How the results depend on the processing

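The alternatives in which scanner files were exchanged, arrays other than single ones were left out, one slide was fitted alone or probes ending in _s or _as were dropped were chosen after seeing the data, and the others were planned. Over all alternatives the 141 named probe results kept direction and side of the threshold in 5515 of 6604 comparisons, lost the threshold in 1087 and turned in 2. The 42 list calls kept both in 1694 of 1894, lost it in 196 and turned in 4. Single arrays left out make up most of these comparisons, and other settings lost more. Of the 183 results of both kinds a dye intercept per slide lost 91, scale normalization 65, the deposited log ratios 60 and the exchanged scanner files 53. The deposited log ratios were fitted with their columns as titled, so that setting also carries the exchange of 2 arrays. Agilent's processed signals lost 27. An adjusted p under 0.01 lost 67 of 141, the tissue loop alone 48 of 140, the rhizome loop alone 26 of 43, slide 3 alone 108 of 129 and slide 4 alone 28 of 37. Except where a setting has fewer arrays or probes, the cause was not tested. Signal over background, as low as 5.782 in one channel, limits dim probes. An alternative restricted to ginger probes was not run, because names do not separate species. No paired analysis was possible because the replicate numbers only tell apart both arrays of one condition pair. The median of all probes moved by over 0.1 only within slide 3 alone, by 0.107 for the age change of root against rhizome.

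Values are given in the order of the comparisons and only where a count moved by over 1.5 times. Ages are written as months, as in 3 against 2. Without background correction all rhizome ages gave 254, 3 against 2 gave 3, 6 against 4 gave 5, 7 against 6 gave 9 and root age 109. Agilent's processed signals gave 1 for 3 against 2, 0 for 6 against 4 (limma, 1474 at an unadjusted p under 0.05) and 2 for 7 against 6. Median centring gave 68 for 6 against 4 (10.3% upwards, against 100% of 2), 574 for 7 against 2, 400 for leaf age, and 51 and 43 for the age changes of leaf and root against rhizome. Scale normalization gave 1145 for all ages, 54 for 3 against 2, 373 for 6 against 4 (47.2% upwards), 62 for 7 against 6 (32.3% upwards, against 6.67%), 42 for leaf age, 16 for root age, 3999 for leaf against rhizome, 1263 for root against rhizome, 3730 for leaf against root, 3 and 12 for the age changes and 31 rhizome-higher probes.

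In the value table the 2 exchanged columns were fitted as titled. The value table gave 33 for all ages, 6 for 6 against 4, 3 for 7 against 6, 201 for 7 against 2, 438 for leaf age, 35 for root age, 1596 for root against rhizome, 0 for the age change of root (limma, 1312 at an unadjusted p under 0.05) and 19 rhizome-higher probes. The strict filter gave 4 for 6 against 4. Without a dye term all ages gave 42, 6 against 4 gave 0 (limma, 1201 at an unadjusted p under 0.05), 7 against 6 gave 5, 7 against 2 gave 493, root age 32 and the age change of leaf 25. Array weights gave 1725 for all ages, 176 for 3 against 2, 51 for 6 against 4, 311 for 7 against 6, 1620 for 7 against 2, 2380 for leaf age, 198 for root age and 1396 and 52 for the age changes. Separate channels gave 3302 for all ages, 62 for 3 against 2, 518 for 6 against 4, 1253 for 7 against 6, 2976 for 7 against 2, 2029 for leaf age, 507 for root age, 5025 for root against rhizome, 648 and 221 for the age changes and 612 rhizome-higher probes.

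The slide as a random block (within-slide correlation 0.03544) moved no count by over 1.5 times. A dye intercept per slide gave 2 for 3 against 2, 9 for 7 against 6, 19 for leaf age, 0 for root age, 3610 for leaf against rhizome, 628 for root against rhizome, 0 and 0 for the age changes and 16 rhizome-higher probes (limma, 1052, 1274 and 894 at an unadjusted p under 0.05 where 0). Slide 3 alone, with 2 residual degrees of freedom and the array labelled replicate 2 among its 8 arrays, gave 0 for 7 against 2, leaf age, root age, the 3 tissue contrasts, both age changes and rhizome-higher probes (limma, 673, 289, 512, 547, 76, 316, 270 and 226 at an unadjusted p under 0.05). Slide 4 alone gave 0 for all ages, 6 against 4, 7 against 6 and 7 against 2 (limma, 1962, 915 and 2081 at an unadjusted p under 0.05). In slide 3 alone the cell division list in root age turned to 0.161, a hypersensitive-induced response protein in the age change of leaf to -0.383 and a beta-1,3-glucanase among the rhizome-higher probes to -0.582. In slide 4 alone sucrose metabolism in 3 against 2 turned to -0.603 and cell wall genes in 7 against 6 turned at -0.0279.

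Averaging both arrays labelled leaf 2 months against root 7 months gave 315 for all ages, 23 for 6 against 4, and 238 and 42 for the age changes. Leaving out the array with the leaf tissue label gave 1 for 6 against 4 and 173 for 7 against 6. A minimum log2 difference of 1 gave 71 for all ages, 461 for 7 against 2, 4186 for leaf against rhizome, 1658 for root against rhizome and 3390 for leaf against root. An adjusted p under 0.01 gave 20 for all ages, 1 for 7 against 6, 149 for 7 against 2, 115 for leaf age, 13 for root age, 1478 for root against rhizome, 10 and 6 for the age changes and 61 rhizome-higher probes. The rhizome loop alone, with 5 residual degrees of freedom, gave 0 for all ages, 1 for 3 against 2, 0 for 6 against 4, 0 for 7 against 6 (limma, 2054 and 1867 at an unadjusted p under 0.05) and 33 for 7 against 2. The tissue loop alone gave 172 for leaf age, 12 for root age, 0 and 0 for the age changes (limma, 1424 and 1270 at an unadjusted p under 0.05) and 132 rhizome-higher probes.

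With 2 scanner files exchanged 6 against 4 gave 33, 7 against 6 gave 7, root age 24, root against rhizome 1514, the age changes 36 and 0 (limma, 1030 at an unadjusted p under 0.05) and rhizome-higher probes 7. Without these arrays 3 against 2 gave 1, 6 against 4 gave 5, root age 31, the age change of root 5 and rhizome-higher probes 140. Without these and the array labelled replicate 2 all ages gave 577, 3 against 2 gave 7, 6 against 4 gave 58, 7 against 6 gave 24, 7 against 2 gave 1544, leaf age 1481, root age 40 and the age change of leaf 660. Without these 3 and the array with the leaf tissue label they gave 550, 3, 1, 278, 1638, 1575, 33 and 629. Without probes ending in _s or _as 6 against 4 gave 4 and 7 against 6 gave 9. Camera with an estimated correlation left 1 list call.

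Leaving out 1 array at a time gave 32 to 469 for all ages, 0 to 4 for 3 against 2, 0 to 0 for 4 against 3, 1 to 97 for 6 against 4, 0 to 173 for 7 against 6 (limma, 1046 and 1420 at an unadjusted p under 0.05 for the arrays that gave 0), 134 to 1637 for 7 against 2, 120 to 1524 for leaf age and 25 to 403 for root age. It gave 5984 to 7706 for leaf against rhizome, 1793 to 3359 for root against rhizome, 5150 to 7029 for leaf against root, 9 to 781 and 3 to 122 for the age changes, 123 to 344 rhizome-higher probes and 33 to 48 list calls. The lowest counts came without the array that compares both ages directly for all ages and 7 against 2 (rhizome 7 months against 2 months), for leaf age and the age change of leaf (leaf 2 months against 7 months) and for the age change of root (root 7 months against 2 months). Without rhizome 3 months against 4 months the cell division list in 4 against 3 turned to 0.114, and single arrays otherwise gave means down to -0.288.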

Other observations

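The tests of the Cy3 channel of the array labelled replicate 2 and of its residuals were chosen only after the result was seen. The other tests in this part were planned.

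Cysteine proteases of the papain type, the family of the ginger zingipains, differed between organs probe by probe. In root against rhizome 6 of 28 were higher and 2 lower (8 adjusted over the list alone; camera adjusted p = 0.606), with one at 3.89 ± 0.321 (adjusted p = 9.86e-07, above background in 7 of 15 rhizome channels) and others at 2.95 and 2.94. In leaf against rhizome 9 were higher and 4 lower (16 adjusted over the list alone; camera adjusted p = 0.242), among them a cathepsin B-like protease at 2.75. In the maturing rhizome one probe named protease gp2b was higher by 2.33 ± 0.485 (adjusted p = 0.0137, saturated in 3 of 8 channels of 7 months) and another lower at -1.64 ± 0.386 (adjusted p = 0.0222, 7 of 8 channels of 7 months above background). From 4 to 6 months the median of this list was 0.0201, its mean -0.261 and its test downwards without passing (camera adjusted p = 0.078). Among O-methyltransferases and cytochrome P450s 30 of 152 were higher in root than in rhizome and 18 lower (55 adjusted over the list alone; camera adjusted p = 0.606), with CYP71C3v2 at 3.45 (13 of 15 rhizome channels above background) and an O-methyltransferase at 4.34 ± 0.37 (above background in 10 of 15 rhizome channels).

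Of the flavonoid enzymes 13 of 34 probes were lower in leaf than in rhizome and 8 higher (21 adjusted over the list alone; camera adjusted p = 0.132), with flavonoid 3'-hydroxylase at -3.72 and flavonol synthase at -1.72. Of the chalcone synthase family 10 of 24 were lower in leaf than in root and 2 higher (12 adjusted over the list alone; camera adjusted p = 0.0738). Isoprenoid precursor enzymes split in leaf against rhizome, 6 of 30 higher and 8 lower (14 adjusted over the list alone; camera adjusted p = 0.522), with a median of -0.15, a mean of 0.0156 and a test pointing down. Geranylgeranyl diphosphate synthase, which feeds chlorophyll and carotenoids, was at 4.86 ± 0.459. The ethylene-forming enzyme ACC oxidase was higher in root than in rhizome by 4.23 ± 0.527 (adjusted p = 6.78e-05). A MADS box gene was higher in rhizome of 7 than of 2 months by 4.40 ± 1.02 (adjusted p = 0.0217). It is not among the 16 named genes of that comparison, whose rule also asks for the sign of the fit on direct arrays and for 1 probe per name.

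The array labelled leaf 2 months against root 7 months, replicate 2, stood apart in its residual SD, 1.67 against 0.677 to 1.07 for the 23 others. Its log ratios had r = 0.178 with the prediction for its title, where the 13 other arrays with leaf or root RNA ranged from 0.183 to 0.902, and r = 0.47 with rhizome 2 months against root 7 months, higher in 10 of 10 random subsets of the probes. Root 7 months against root 2 months also had a low r, 0.183, and leaf 7 months against root 7 months had 0.752 against 0.872 for another pair. Both hold root of 7 months, and the array labelled replicate 2 stayed in the fits that predicted them. Their r therefore cannot show whether a low or bettered r is particular to that array. Its own best r was 0.601, for rhizome 2 months against rhizome 7 months. In the tissue loop 1 pair has no array, rhizome 2 months against root 7 months, while 2 arrays are titled leaf 2 months against root 7 months. Rhizome in place of leaf is thus a candidate explanation, and the content of the array stays open. Its Cy3 photosynthesis percentile was 30, below the 56 of the lowest other leaf channel, which argues against leaf RNA in that channel. A signal shared with the rhizome 2 months against 4 months array (r = 0.528 across probes) is not decided by their residual correlation of 0.162, under the 95th percentile of 0.418 in other pairs, because the residuals were taken against a title that the Cy3 channel contradicts; no biological explanation was tested, and the array was refitted under no other label.

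The array titled rhizome 4 months against rhizome 6 months with a leaf tissue label had a photosynthesis percentile of 26.9, within the range of the other rhizome-only arrays (highest 31.1) and far from the 66.7 of the array of leaf against leaf. This argues against leaf RNA on it. Its r with its titled pair was -0.0312, where rhizome-only arrays ranged from -0.267 to 0.608, so whether its ages are right stays open. Of the other arrays with rhizome of 4 months, r was -0.267 for 3 against 4 months, -0.133 for 2 against 4 months and 0.399 for 4 against 7 months. No biological explanation was tested.

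For the other counts, 100 assignments of the condition pairs to the arrays were drawn, the real one included. Only the real one was as large for leaf against rhizome (7130, highest other 381), root against rhizome (2913, highest other 8) and leaf against root (6198, highest other 910). The same held for leaf of 7 against 2 months (668, highest other 16) and rhizome-higher probes (247, highest other 0). For rhizome of 7 against 2 months 2 were as large as 937 (highest other 1402), and for all rhizome ages 2 as 139 (highest other 141). From 4 to 6 months 2 were as large as 2 (highest other 5), and from 6 to 7 months 4 as 15. Drawn assignments exchange tissues between arrays, so tissue differences enter their spread between arrays. Shares this low speak against titles without bearing on the arrays, but cannot decide whether age changed expression. The highest other for 6 to 7 months, 1044, points to a structure of the samples. That structure can be the tissue differences themselves, and what these assignments followed was not tested. Chance cannot be excluded for root of 7 against 2 months, where 5 were as large as 72 and the highest other, 1194, points to such a structure too, nor for the list shifts (15 as large as 42, highest other 53). From 2 to 3 and from 3 to 4 months the real counts were 0 (limma, 647 and 355 at an unadjusted p under 0.05), so 100 of 100 were as large in both, with highest others of 1 and 989.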
